A study of Mus musculus with 9 samples.

How the data were processed

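Total RNA of mouse embryonic stem cells, purified with a column kit, was labelled (50 ng per sample) with Cy3 and hybridised to Agilent 1-colour arrays, 1 array per sample and 9 in all. The deposited scanner files hold spot intensity on a linear scale, written by Agilent Feature Extraction 10.7.3.1 per the file headers. The processed signal in them is the intensity after background subtraction and detrending within the array, with low spots replaced by a surrogate and no scaling between arrays. The files also hold the raw mean signal, the local background and yes-or-no spot qualities, the other values deposited per the file headers. The values of the deposited series matrix are the mean signal of each spot, an intensity equal to that of the scanner files for 100% of values, with no centring and column medians between 94.5 and 140. All of its columns were matched to a sample, so 0 were left over.

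Each array had 62976 spots, of which 59305 were not controls and stood for 55681 probes. Median local background lay between 29 and 46.5, the 75th percentile of the processed signal between 346 and 471, and between 148 and 188 spots per array were marked as outliers. Probes were named through their RefSeq accession where the reference of assembly GRCm38.p6 held it (27235) and otherwise kept the name in the files (28446), while probe positions are those of mm9 in the files. Exons and introns of mm9 were not analysed here.

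Groups were taken from the labels, 3 arrays each. Control spots and outlier spots were left out and the spots of a probe averaged. Values were log2 of the processed signal minus the log2 of the array's 75th percentile. A probe was kept if it lay well above background on all 3 arrays of at least 1 group, which left 27539 probes, and 2 were left out because every spot was an outlier on an array. Each gene name was represented by its brightest probe over all 9 arrays, which gave 19914 genes, 6847 of them with predicted or identifier names. For a gene above background on no array of its lower group, the change is given as "at least N-fold", computed with each array of that group at no less than the lowest log2 value its probes reached while well above background.

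The 3 comparisons were made in 1 limma fit of 3 group means (lmFit and eBayes, two-sided moderated tests), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Xpc was tested on its own, adjusted over the 3 comparisons. The design, the comparisons, the gene lists and the rule for named genes were fixed before the data were examined. By that rule the text names, in each comparison, Xpc, the stem cell factors Pou5f1, Sox2, Nanog, Klf4, Esrrb and Zfp42, the partners Rad23b and Cetn2, the 10 largest rises and 10 largest falls that passed without overlap of the groups and above background on all arrays of at least 1 group, up to 3 passing members of each list in each direction, and the genes that passed in both comparisons with floxed cells. A few results that the rule names are not reported here. Predicted and clone names were counted but not named, 65 and 90 of the genes that passed in the comparisons of null with floxed and with induced cells. Genes that passed over a list alone in the induced cells, and list members named although they did not pass, were chosen after their values were seen.

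The 26 lists were pluripotency, Oct3/4-Sox2 targets, primed epiblast, trophectoderm, primitive endoderm, primitive streak and mesoderm, neuroectoderm, nucleotide excision repair, p53 targets, G2/M cell cycle, cholesterol biosynthesis, hypoxia and glycolysis, oxidative stress (Nrf2 targets), integrated stress response (Atf4 targets), interferon response, 2-cell-like, germline genes, imprinted genes, FGF-ERK and immediate early, Wnt-beta-catenin targets, LIF-Stat3 targets, neighbours of Xpc, Y chromosome and Xist, and 3 of cell type markers (fibroblast, epithelial, blood and endothelium). Each was tested against the other genes with camera (preset correlation 0.01), adjusted within a comparison. None of the calls made in this way held with an estimated correlation. Overlap of the comparisons with floxed cells was set beside 100 simulations of unchanged groups against the same floxed arrays.

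The steps were tested on simulated data of the same size with 200 changed genes. Of genes changed by 2 on the log2 scale 84% to 96% were recovered, of those changed by 1 between 64% and 78%, and between 3.57% and 6.43% of the calls were false. Of 100 unchanged lists in each comparison, 1, 0 and 1 had a camera p under 0.05. A first version of this check used a single unchanged list, which fell under 0.05 by chance, and was replaced by the 100. Simulated genes were independent of each other and had no slide differences. The check therefore cannot show how camera with the preset correlation behaves where list members correlate. In the data the estimated correlation was as high as 0.61, for cholesterol biosynthesis.

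Alternatives were quantile normalization, median centring, normexp background correction (offset 50), the values of the series matrix, no filter and a filter over all 9 arrays, the mean of a gene's probes and every probe alone, a fit of only the 6 arrays compared, eBayes with trend and robust, array weights, replicate number or slide as a block, each array left out in turn, and camera with an estimated correlation and fry for the lists. Slide as a random block and a fit within slide 3 were added after seeing the data. R 4.3.3, limma 3.58.1, statmod 1.5.0 and the package data.table in version 1.17.8 were used.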

Results

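Gene expression was measured in mouse embryonic stem cells, the self-renewing cells of the early embryo kept in culture, whose Xpc gene is flanked by loxP sites (floxed) so that Cre recombinase can delete it. Xpc protein recognises DNA damage for nucleotide excision repair and, together with Rad23b and Cetn2, is also known as a partner of the stem cell factors Oct3/4 and Sox2 in transcription. RNA came from 3 groups: floxed cells with no deletion, cells 4 days after the deletion was induced, and a subclone of Xpc-null cells. Each group had 3 arrays, 9 in all, and their number limits the precision of every value. Whether the arrays of a group stand for separate cultures is not stated, so the p-values may measure technical spread alone. On each array between 47.4% and 57.9% of the spots lay well above background, and no spot was saturated. The arrays sat on 3 slides, each scanned separately: slide 1 held floxed arrays 1 and 2, slide 2 held floxed array 3 and null array 3, and slide 3 held the 3 induced arrays and null arrays 1 and 2.

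Null arrays lay apart from induced arrays and from floxed arrays 1 and 2 along the first principal component of the 19914 genes tested, which held 47.3% of the variance. Floxed array 3 lay on the null side of that component, at 24.2 against -32.6 and -33.9 for floxed arrays 1 and 2. The second component, with 15.0%, set the slide 2 arrays (floxed 3 at -27.9, null 3 at -18.6) apart from null arrays 1 and 2, both at 17.4 or above. Across genes, which are not independent replicates, floxed array 3 correlated at r = 0.993 with null array 3 and at 0.986 with floxed arrays 1 and 2. Its distance from the mean of floxed arrays 1 and 2 had an SD over genes of 0.492 on the log2 scale, against 0.284 between those 2 arrays.

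**Figure D1:**
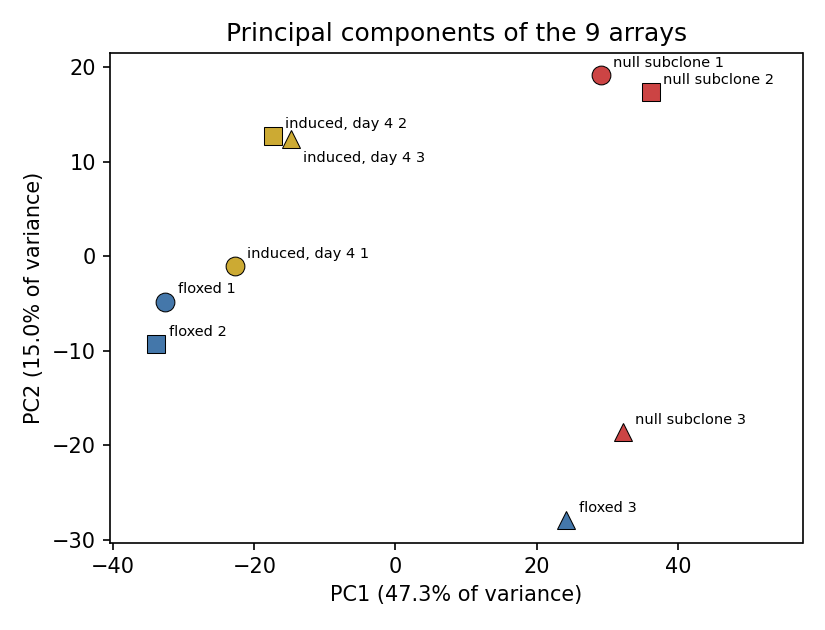
First and second principal components of log2 expression in the 9 arrays, with the percentage of variance on each axis (47.3% and 15.0%); each point is an array, coloured by group and labelled with group and replicate. Floxed array 3 lies at 24.2 on the first component, near the null arrays at 29.1 to 36.2, and both arrays of slide 2 lie below the rest on the second component.

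The Xpc transcript itself was lower in every induced and every null array than in every floxed array. Relative to the 75th percentile of its array, the log2 signal was 0.59, 0.55 and 0.16 in floxed arrays 1 to 3, -1.11, -0.68 and -1.05 in induced arrays 1 to 3, and -0.85, -1.53 and -1.37 in null arrays 1 to 3. The group means were 0.43 ± 0.23 (SD, n = 3) in floxed, -0.95 ± 0.23 (n = 3) in induced and -1.25 ± 0.35 (n = 3) in null arrays. Induced cells thus held 38.4% of the floxed level (log2 change -1.38, limma adjusted p = 0.000122 over the 3 comparisons) and null cells 31.1% (-1.68, limma adjusted p = 5.16e-05). Between null and induced cells the difference of -0.30 did not pass (limma adjusted p = 0.167), but without null array 1 it was -0.50 and passed. Adjusted over all 19914 genes, the limma p-values were 0.224, 0.00584 and 0.386 in the same order. With slide as a block the 3 changes were -1.29, -1.53 and -0.25, of which the first 2 passed over the 3 comparisons. The array has 1 probe for Xpc, on chromosome 6 of mm9 from 91439856 to 91439915 on the minus strand, with the sequence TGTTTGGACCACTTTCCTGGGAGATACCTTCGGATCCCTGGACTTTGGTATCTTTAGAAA. It lay well above background on all 9 arrays, and whether it falls inside the deleted part of the gene is not known.

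**Figure D2:**
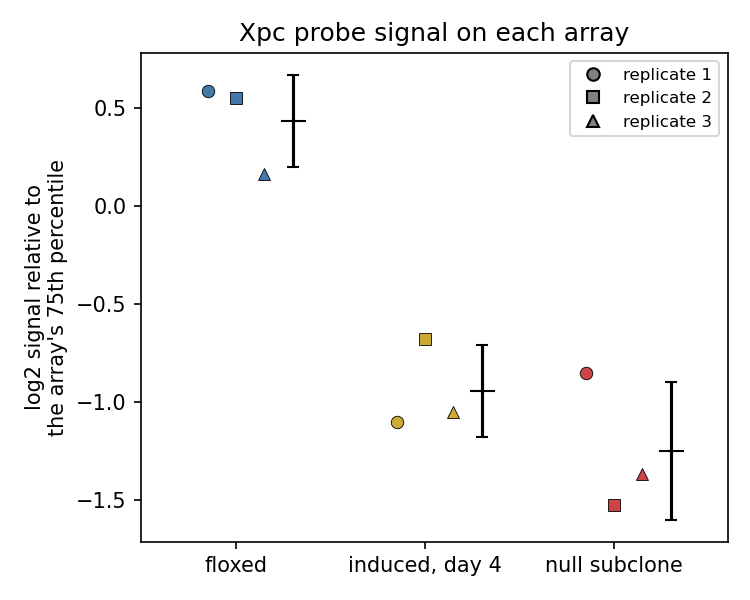
Log2 signal of the Xpc probe relative to the 75th percentile of each array, by group; points are arrays, marker shapes are replicate numbers and bars are the mean with the SD of 3 arrays. All 6 arrays of the induced and null groups, at -0.68 or below, lie under the lowest floxed array at 0.16.

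The comparison of induced with floxed cells asks what changed within 4 days of the induced loss of Xpc. The sample titles mark induced cells +Tx and floxed cells -Tx. No group was induced without losing Xpc, so effects of the induction or of Cre cannot be told apart from those of Xpc loss. Besides Xpc, which was tested alone, 1 gene passed: Tmem95, which encodes a membrane protein of sperm, rose at least 1.19-fold. Its log2 signal was -3.25 ± 0.21 (SD, n = 3) in induced and -5.09 ± 0.17 (n = 3) in floxed arrays, and it lay above background on none of the floxed arrays (limma adjusted p = 0.00803). None of the stem cell factors passed: Pou5f1, which encodes Oct3/4, was at a log2 difference of -0.03 (adjusted p = 0.997), Sox2 at 0.02, Nanog at 0.03, Klf4 at 0.24 (adjusted p = 0.972), Esrrb at 0.23 (-0.04 at its other probe) and Zfp42 at 0.12. Rad23b at 0.04 and Cetn2 at 0.08, the partners of Xpc, did not pass either. Leaving out floxed array 3 gave Sox2 (-0.11), Nanog (-0.15), Klf4 (-0.16), Esrrb (-0.09) and Zfp42 (-0.11) the opposite sign, and with slide as a block Klf4 was at 1.03 and Esrrb at 0.89, none past the test. With limma 1178 of the 19914 genes had an unadjusted p under 0.05. Without induced array 1 Tmem95 no longer passed (adjusted p = 0.0876) and 0 genes did, and without floxed array 3 the count was 145. Without floxed array 1 or floxed array 2 it was 2 each time, and over all alternatives the adjusted p of Tmem95 ran from 0.0031 to 0.817. No slide held both floxed and induced arrays, so a comparison blocked by slide rests on floxed array 3 alone, reached through the null arrays, and floxed arrays 1 and 2 drop out. It gave 174 genes, Tmem95 among them (adjusted p = 0.0427), and with slide as a random block 0 passed.

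No gene on any of the 26 lists changed past the genome-wide threshold between induced and floxed cells. Adjusted over the list alone, Lefty2 of the Oct3/4-Sox2 targets and Aldoc of the hypoxia and glycolysis list rose, while Krt8 and Krt19 (epithelial keratins), Nes (a neural intermediate filament) and Tagln (an actin-binding protein of contractile cells) fell. As sets, 11 lists differed from the other genes by camera with the preset correlation, and none of the 11 did with an estimated correlation. The 13 epithelial genes measured had a median log2 change of -0.29 (adjusted p = 5.21e-07, and adjusted p = 0.515 with an estimated correlation). Fibroblast genes (13 measured) were at -0.22 (adjusted p = 0.0075, and adjusted p = 0.515 with an estimated correlation) and trophectoderm genes (17) at -0.18 (adjusted p = 0.0207, and adjusted p = 0.515 with an estimated correlation). The 26 p53 targets had a median of -0.08 (adjusted p = 0.00468) and the 13 Wnt targets one of -0.10 (adjusted p = 0.0355), each at adjusted p = 0.544 with an estimated correlation. The same adjusted p = 0.544 with an estimated correlation held for 22 Oct3/4-Sox2 targets at 0.09 (adjusted p = 0.0156), 24 G2/M genes at 0.10 (adjusted p = 0.00712), and 5 genes of the list Y chromosome and Xist at 0.23 (adjusted p = 0.0317). Xist itself was not among the genes measured. Cholesterol biosynthesis genes (25) were at 0.13 (adjusted p = 0.00468, and adjusted p = 0.681 with an estimated correlation), hypoxia and glycolysis genes (27) at 0.14 (adjusted p = 0.0242, and adjusted p = 0.579 with an estimated correlation) and LIF-Stat3 targets (16) at 0.20 (adjusted p = 0.0273, and adjusted p = 0.582 with an estimated correlation).

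With slide as a block, and so against floxed array 3 alone, the induced medians turned for cholesterol biosynthesis (-0.35), hypoxia and glycolysis (-0.27) and G2/M (-0.0021). Epithelial genes stood at -0.46, fibroblast and trophectoderm genes at -0.12 each, p53 targets at -0.06, Wnt targets at -0.54, LIF-Stat3 targets at 0.35, Y chromosome and Xist at 0.21 and Oct3/4-Sox2 targets at 0.11. Of these, epithelial genes, Wnt targets and LIF-Stat3 targets passed camera, as did cholesterol biosynthesis in the opposite direction and primed epiblast genes, whose median moved from -0.14 (adjusted p = 0.178) to -0.74. Pluripotency genes (0.17, from 0.07), interferon genes (-0.44, from -0.03) and 2-cell-like genes (-0.34, from 0.14) also passed camera when blocked and had not with all arrays and no block. Leaving out 1 array ended 9 of the 11 calls, all but those of epithelial and fibroblast genes. Without floxed array 1 cholesterol biosynthesis (0.02) and hypoxia and glycolysis (0.06) were lost, and without floxed array 2 those lists (0.07 and 0.06), trophectoderm (-0.14), p53 targets (-0.05) and Y chromosome and Xist (0.23). Without floxed array 3 trophectoderm (-0.16), Oct3/4-Sox2 targets (0.0066), G2/M (0.07), Wnt targets (-0.09), LIF-Stat3 targets (-0.04) and Y chromosome and Xist (0.10) were lost. Without induced array 1 Oct3/4-Sox2 targets (0.07), G2/M (0.08), hypoxia and glycolysis (0.11), Wnt targets (-0.18) and LIF-Stat3 targets (0.20) were lost. Y chromosome and Xist (0.20) was lost without induced array 2, that list (0.12), trophectoderm (-0.14) and Wnt targets (-0.07) without induced array 3, and Wnt targets (-0.10) without null array 3.

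In floxed array 3, which stood apart from floxed arrays 1 and 2, cholesterol biosynthesis genes lay at a median of 0.58 and hypoxia and glycolysis genes at 0.50 above those arrays, and fibroblast genes at -0.22. Targets of Atf4, the factor that drives the integrated stress response, had a median of 0.10 (21 measured, adjusted p = 0.553) between induced and floxed cells. Without floxed array 3 that median was -0.23, and with slide as a block it was 0.53, each past camera with the preset correlation, as were 0.21 and 0.23 without floxed array 1 or 2. Pluripotency genes (0.08 and 0.17) and primed epiblast genes (-0.30 and -0.27) also passed without floxed array 1 or 2. When floxed array 3 was left out 2-cell-like genes (0.56), primitive streak and mesoderm genes (0.18) and blood and endothelium markers (0.26) passed. Germline genes passed without floxed array 1 (0.22), induced array 3 (0.21) or null array 3 (0.18).

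The comparison of null with floxed cells asks what lasting loss of Xpc changed, in cells that had also been subcloned. Genes that fell far in null cells included an actin, a collagen and a transcription factor of trophectoderm, the outer lineage of the blastocyst. Acta2, the smooth muscle actin on chromosome 19 of mm9 (probe from 34316060 to 34316119), fell by 3.55 on the log2 scale (SE 0.28, limma adjusted p = 0.000764), from 2.25 ± 0.63 (SD, n = 3) to -1.30 ± 0.14 (n = 3). Col1a1, a chain of type I collagen on chromosome 11 (94813115 to 94813174), fell by 2.39 (adjusted p = 0.000631), from -0.59 ± 0.25 (n = 3) to -2.99 ± 0.21 (n = 3). Cdx2, that transcription factor, on chromosome 5 (148112547 to 148112606), fell at least 3.85-fold (adjusted p = 0.00452) and lay above background on none of the null arrays.

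In all, 368 genes passed between null and floxed cells, of which 147 rose and 221 fell. The other 8 of the 10 largest falls included growth and signalling factors. Csf1, a macrophage growth factor, fell at least 6.54-fold (adjusted p = 0.000631) and Ccn4, a matrix protein induced by Wnt signalling, at least 6.41-fold (adjusted p = 0.000764), neither above background on a null array. Tgfb2, a growth factor on chromosome 1 (188449333 to 188449392), fell by 2.87 (SE 0.20, adjusted p = 0.000631) and was above background on 1 of 3 null arrays. Wnt4, a Wnt ligand, fell by 2.55 (SE 0.17, adjusted p = 0.000631), and its other probe gave -1.69. Also among them were Pmp22, a myelin protein (-3.87, above background on 2 of 3 null arrays, -0.86 at its other probe), the protease Prss23 (-3.50, on 1 of 3), the muscle cofactor Ankrd1 (at least 2.44-fold lower) and the skeletal muscle actin Acta1 (-2.73). The 10 largest rises were smaller. Ceacam20, a cell adhesion protein, rose by 1.78 (SE 0.13, adjusted p = 0.000631), from -2.35 ± 0.27 (n = 3) to -0.57 ± 0.08 (n = 3). At its other probe the rise was only 0.64. Slc4a5, a bicarbonate transporter, rose by 1.36 (adjusted p = 0.000898) and Egr1, an immediate early transcription factor, by 1.43 (adjusted p = 0.0213).

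The other 7 of those rises were the Fc receptor Fcgr2b (1.86), the potassium channel Kcnj16 (1.63), Teddm3 (2.28), the myosin Myo1g (1.52), Arhgap30 (1.40), the oxygen-sensing hydroxylase Egln3 (1.27, and 0.89 at its other probe) and the cell cycle factor E2f2 (1.20), with adjusted p-values between 0.00429 and 0.0388. In floxed cells Teddm3 was above background on 2 of 3 arrays, and Fcgr2b, Kcnj16 and Arhgap30 on 1 of 3. The stem cell factors did not pass: Pou5f1 was at -0.55 (adjusted p = 0.275), Nanog at -0.60 (adjusted p = 0.134), Esrrb at -0.43 (adjusted p = 0.308), Sox2 at -0.18 (adjusted p = 0.404), Zfp42 at -0.13 (adjusted p = 0.687) and Klf4 at -0.05 (adjusted p = 0.938). Rad23b at 0.14 (adjusted p = 0.44) and Cetn2 at 0.48 (adjusted p = 0.129) did not pass. These results rested on floxed array 3: without it Nanog (-0.78), Esrrb (-0.76), Klf4 (-0.44), Zfp42 (-0.37), Sox2 (-0.32) and Cetn2 (0.67) passed, and Pou5f1 (-0.59) and Rad23b (0.22) did not. With slide as a block Klf4 (0.75), Zfp42 (0.23), Esrrb (0.22), Sox2 (0.14) and Rad23b (-0.09) had the opposite sign, none past the test.

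**Figure D3:**
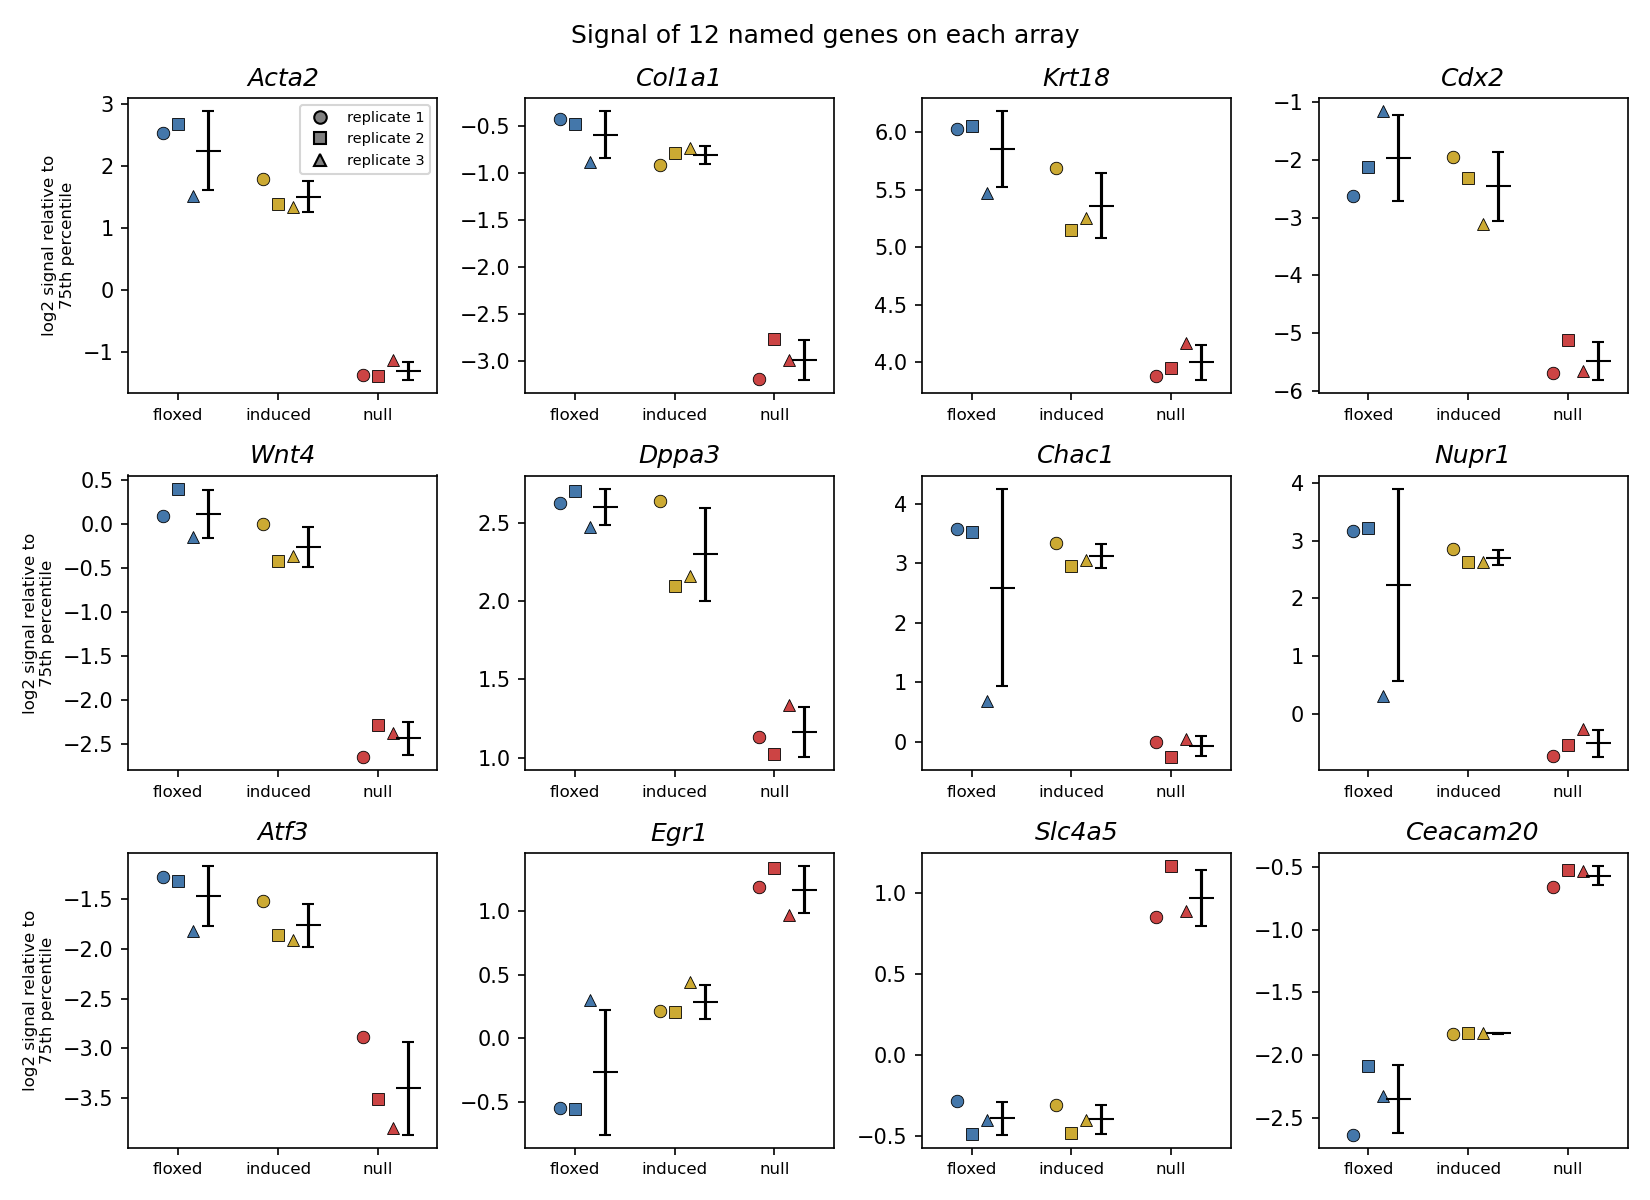
Log2 signal relative to the 75th percentile of each array for 12 named genes in the 3 groups; points are arrays, marker shapes are replicate numbers and bars are the mean with the SD of 3 arrays. Acta2 lies at 2.25 in floxed and -1.30 in null arrays, and Chac1 at 3.12 in induced and -0.07 in null arrays.

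Of 17 trophectoderm markers measured, Cdx2 among them, 8 fell and 9 did not pass, and adjusted over the list alone 8 fell. Their median was -0.50 (camera adjusted p = 0.000148, and adjusted p = 0.166 with an estimated correlation). The keratins Krt18 (-1.86, adjusted p = 0.00298) and Krt8 (-1.64, adjusted p = 0.000764) and the transcription factor Hand1 (-1.42, adjusted p = 0.016, above background on 1 of 3 null arrays) were among the falls. Of 13 fibroblast markers 6 fell (9 fell and 1 rose adjusted over the list alone), among them Twist2, a mesenchymal transcription factor (at least 1.91-fold lower), Tagln (-2.07) and the collagens Col1a2 (-2.07) and Col3a1 (-1.24). Their median was -0.60 (adjusted p = 1.28e-06, and adjusted p = 0.0543 with an estimated correlation). Epithelial markers (13) had a median of -0.28 (adjusted p = 0.0207, and adjusted p = 0.569 with an estimated correlation), with 3 falls, of Krt19 (-1.56) and of Krt8 and Krt18, which the trophectoderm list also holds, and the same 3 adjusted over the list alone. The list was divided, with 6 markers higher and 7 lower in null cells. Blood and endothelium markers (8) did not differ as a set by camera (0.40, adjusted p = 0.191), no member passed over all genes, and adjusted over the list alone 4 rose (Cd34, Tal1, Gata1 and Hbb-bh1) and 1 fell (Runx1). By fry, which does not compare a list with other genes, that list moved upward (adjusted p = 0.0434).

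Targets of Atf4, the list of the integrated stress response, had the median farthest from 0. Of 21 measured, 6 fell and 15 did not pass, and adjusted over the list alone 13 fell. Atf3, a stress-induced transcription factor above background on 1 of 3 null arrays, changed by -1.93 (adjusted p = 0.00758), Atf4 itself by -1.31 (adjusted p = 0.04), and Mthfd2, an enzyme of folate metabolism, by -1.0 (adjusted p = 0.0433). Chac1, which degrades glutathione, was at -2.66 (adjusted p = 0.0788) and the stress regulator Nupr1 at -2.75 (adjusted p = 0.0747). The median was -1.0, or -0.81 with genes below background set to their bound (adjusted p = 3.91e-09, and adjusted p = 0.38 with an estimated correlation). Floxed array 3 already lay at a median of -0.76 from floxed arrays 1 and 2, and the null arrays at -0.30 from floxed array 3.

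Genes of cholesterol biosynthesis lay higher in null cells. Of 25 measured, 2 rose (Insig1, a regulator of the pathway, 0.89, adjusted p = 0.0319, and the enzyme Msmo1, 0.70, adjusted p = 0.0448), and adjusted over the list alone 19 rose. The median was 0.63 (adjusted p = 2.98e-10, and adjusted p = 0.38 with an estimated correlation), and floxed array 3 lay at 0.58 above floxed arrays 1 and 2. Hypoxia and glycolysis genes (27) had a median of 0.36 (adjusted p = 9.29e-05, and adjusted p = 0.38 with an estimated correlation), with 2 rises, of Egln3 and the glycolytic enzyme Aldoc (0.93), and 12 adjusted over the list alone. Floxed array 3 lay at 0.50 above floxed arrays 1 and 2 in that list. Primed epiblast genes (17) had a median of 0.34 (adjusted p = 0.00192, and adjusted p = 0.38 with an estimated correlation) with 0 genes past the limma test and 4 rises adjusted over the list alone, and floxed array 3 lay at 0.57.

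A further pair of lists differed as sets. FGF-ERK and immediate early genes (20 measured) had 4 rises, including Etv4 (0.89, adjusted p = 0.022) and the feedback inhibitor Spry4 (0.67, adjusted p = 0.0286), and 1 fall, Phlda1 (-0.79, adjusted p = 0.0312). Their median was 0.26 (adjusted p = 0.00192, and adjusted p = 0.174 with an estimated correlation), and 8 rose and 1 fell adjusted over the list alone. Of 26 p53 targets 2 fell (Plk2, a kinase, -0.60, and Dcxr, a reductase, -0.60), 7 adjusted over the list alone, with a median of -0.20 (adjusted p = 0.00192, and adjusted p = 0.38 with an estimated correlation).

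The remaining lists did not differ from the other genes as sets between null and floxed cells with all arrays and no block. The median log2 changes were -0.11 for pluripotency (adjusted p = 0.235), where the germ cell factor Dppa3 fell by 1.44 (adjusted p = 0.0042) and no other member passed, and -0.11 for Oct3/4-Sox2 targets (adjusted p = 0.613) with 0 genes past the limma test. They were 0.05 for nucleotide excision repair (adjusted p = 0.874) and 0.11 for the neighbours of Xpc on its chromosome (adjusted p = 0.601), with 0 genes past the limma test in either. Medians of 0.10 for G2/M (adjusted p = 0.0712), 0.17 for Nrf2 targets (adjusted p = 0.0712), 0.02 for 2-cell-like genes (adjusted p = 0.874) and -0.19 for Y chromosome and Xist (adjusted p = 0.663) also came with 0 genes past the test. Primitive endoderm genes (0.22, adjusted p = 0.934) included falls of the basement membrane collagens Col4a2 (-1.68) and Col4a1 (-0.76), and primitive streak and mesoderm genes (-0.12, adjusted p = 0.864) a rise of the myosin light chain Myl7 (0.96). In neuroectoderm (0.17, adjusted p = 0.199) Neurod1 (0.91), Gbx2 (0.74) and Nes (0.59) rose. Interferon genes (0.31, adjusted p = 0.146) had a rise of Xaf1 (0.67) and a fall of the chemokine Cxcl10 (at least 4.05-fold), and germline genes (-0.11, adjusted p = 0.547) a fall of the meiotic gene Stra8 (-1.28). Imprinted genes (0.10, adjusted p = 0.697) had a rise of Mirg (0.68) and falls of the growth factor Igf2 (at least 2.26-fold), Ndn (-0.65) and Grb10 (-0.48). Wnt targets (-0.09, adjusted p = 0.613) had a rise of the cyclin Ccnd1 (0.94) and the fall of Cdx2, and LIF-Stat3 targets (0.10, adjusted p = 0.148) the rise of Gbx2. Adjusted over the list alone, the rises and falls were 0 and 1 for pluripotency, 1 and 2 for primitive endoderm, 2 and 0 for primitive streak and mesoderm, 3 and 1 for interferon, 1 and 1 for germline, 3 and 3 for imprinted genes, 2 and 3 for Wnt targets, 3 and 0 for LIF-Stat3 targets and 1 and 1 for Y chromosome and Xist. Mean and median differed in sign for primitive endoderm (mean -0.05), primitive streak and mesoderm (mean 0.03) and nucleotide excision repair (mean -0.02), and camera gave a downward direction for 2-cell-like genes against a positive median.

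With limma 4543 of the 19914 genes had an unadjusted p under 0.05 between null and floxed cells, and 29 of the rises and 114 of the falls were at least 2-fold. In each of the 368 genes the 3 null arrays lay wholly above or below the 3 floxed arrays, which chance gives for 10% of unselected genes, though these were selected by a test on the same arrays. With median centring 78 rose and 216 fell. Without floxed array 3 the count was 4944, with all 368 among them. Without floxed array 1 or 2 it was 92 or 89, without induced array 2 or 3 it was 137 or 126, and without null array 2 or 3 it was 79 or 202. Without null array 1 there were 26 rises and 81 falls.

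With slide as a block, a difference that rests on 1 array of each group on slide 2, 50 genes passed between null and floxed cells, 33 of them among the 368. Csf1, Acta2, Cdx2, Prss23, Ccn4, Tgfb2, Wnt4 and Col1a1 kept passing, at log2 changes of -2.66 for Acta2, -2.23 for Wnt4 and -2.11 for Col1a1. Twist2, Krt19, Col4a2, Cxcl10 and Ankrd1 also kept passing, while Pmp22 (-2.75), Acta1 (-1.68), Krt8 (-1.49), Krt18 (-1.31), Dppa3 (-1.14) and Atf3 (-1.98) no longer did. None of the 10 largest rises passed in that setting (Ceacam20 1.80, Slc4a5 1.29 and Egr1 0.67). The blocked medians were -0.78 for fibroblast markers, -0.54 for trophectoderm markers, -0.27 for epithelial markers, -0.33 for Atf4 targets, -0.17 for p53 targets and 0.20 for FGF-ERK genes, each past the camera test with the preset correlation. Cholesterol biosynthesis (0.13), hypoxia and glycolysis (0.08) and primed epiblast genes (-0.07) did not pass when blocked, while 2-cell-like genes (-0.64) and LIF-Stat3 targets (0.27), which had not passed, did. The epithelial call was lost without floxed array 3 (-0.19), and pluripotency (-0.26), interferon (0.66) and 2-cell-like genes (0.36) then passed. Without null array 3 the epithelial call was lost as well (-0.30), and G2/M (0.12), Nrf2 targets (0.20) and LIF-Stat3 targets (0.17) passed. G2/M and LIF-Stat3 targets also passed without floxed array 1 (0.10 and 0.14) or floxed array 2 (0.11 and 0.21).

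The comparison of null with induced cells asks what differed between lasting and recent loss of Xpc, where the difference in Xpc itself did not pass the test. These groups also differed in subcloning and in the recent induction, whose effects cannot be told apart from how long Xpc had been lost. Members of the integrated stress response list were among the largest falls in null cells: Nupr1 fell by 3.22 on the log2 scale (SE 0.66, limma adjusted p = 0.0462), from 2.70 ± 0.13 (SD, n = 3) to -0.52 ± 0.23 (n = 3). Chac1 fell by 3.19 (SE 0.65, adjusted p = 0.0465), from 3.12 ± 0.20 (n = 3) to -0.07 ± 0.17 (n = 3). Csf1 fell at least 5.89-fold (adjusted p = 0.00185), Acta2 fell by 2.81 (adjusted p = 0.00362) and Cdx2 fell at least 2.73-fold (adjusted p = 0.0115). Pou3f1, a transcription factor of the primed epiblast and of neural cells, rose by 1.67 (SE 0.35, adjusted p = 0.0469). Floxed array 3 had an Xpc signal 1.02 above the highest null array and 0.387 below the lowest other floxed array on the log2 scale. It was already near the null arrays for Pou3f1 (3.46, against 3.55 to 3.78 in null arrays). For Chac1 (0.68 against 3.57 and 3.53) and Nupr1 (0.31 against 3.16 and 3.22) it lay far below floxed arrays 1 and 2. The fit shares its variance among all groups, so the spread of the floxed arrays enters the SEs and p-values of Pou3f1, Chac1 and Nupr1. No floxed array belongs to either group compared here, and the SDs given for Nupr1 and Chac1 within induced and null arrays were 0.23 or lower.

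In all, 438 genes passed between null and induced cells, of which 131 rose and 307 fell. The other 5 of the 10 largest falls were Ccn4 (at least 6.69-fold), Pmp22 (-3.44, above background on 2 of 3 null arrays, with only -0.86 at its other probe against floxed cells), Prss23 (-3.25, above background on 1 of 3), Ankrd1 (at least 1.85-fold) and the protease inhibitor Ctla2a (at least 1.77-fold). Further large rises were those of the vasoactive peptide Edn2 (2.26), the kinase Pim2 (1.77), the growth factor receptor Gfra3 (1.75), the interferon-induced GTPase Igtp (1.52), the guidance protein Sema6a (1.37), Slc4a5 (1.37), Ceacam20 (1.26, with only 0.64 at its other probe against floxed cells) and Arhgap30 (1.23). Floxed array 3 also lay near the null arrays for Edn2 (-0.75), Pim2 (1.37) and Igtp (-0.76). Adjusted p-values of these rises lay between 0.00204 and 0.0465, and Gfra3 was above background on 1 of 3 induced arrays. Pou5f1 (-0.51, adjusted p = 0.293), Sox2 (-0.21, adjusted p = 0.338), Nanog (-0.63, adjusted p = 0.116), Klf4 (-0.28, adjusted p = 0.563) and Zfp42 (-0.26, adjusted p = 0.411) did not pass, nor did Rad23b (0.10, adjusted p = 0.588). Esrrb (-0.66, adjusted p = 0.144) and Cetn2 (0.40, adjusted p = 0.17) did not pass either, but did with slide as a block (-0.66 and 0.43). Nanog, Esrrb and Cetn2 passed at the same log2 changes without floxed array 3.

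Atf4 targets were again the list with the lowest median: of 21 measured 8 fell and 13 did not pass, including falls of Atf3 (-1.64), Atf4 (-1.41) and the lipoprotein receptor Vldlr (-2.24, above background on 1 of 3 null arrays). Adjusted over the list alone 16 fell and 1 rose, and the median was -1.09 (adjusted p = 2.41e-09, and adjusted p = 0.501 with an estimated correlation). That correlation also takes in floxed array 3, which is outside this comparison and lay at -0.76 from floxed arrays 1 and 2 for this list. Of 13 fibroblast markers 6 fell, Col1a1 among them (-2.18), and adjusted over the list alone 8 fell and 2 rose. Their median was -0.59 (adjusted p = 2.02e-05, and adjusted p = 0.0921 with an estimated correlation). Of 17 trophectoderm markers 4 fell (9 fell and 1 rose adjusted over the list alone), with a median of -0.52 (adjusted p = 0.00193, and adjusted p = 0.224 with an estimated correlation). Krt18 (-1.36), Hand1 (-1.16, above background on 1 of 3 null arrays) and Krt8 (-0.98) were among those falls. Primed epiblast genes had a median of 0.47 (adjusted p = 0.000192, and adjusted p = 0.501 with an estimated correlation) with 2 rises, of Pou3f1 and Otx2 (0.47), and 6 adjusted over the list alone.

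Cholesterol biosynthesis genes (25) had a median of 0.44 (adjusted p = 3.11e-06, and adjusted p = 0.572 with an estimated correlation), with 0 genes past the limma test and 9 rises adjusted over the list alone. Hypoxia and glycolysis genes (27) were at 0.31 (adjusted p = 0.00568, and adjusted p = 0.572 with an estimated correlation) with 0 genes past the limma test either way. FGF-ERK genes (20) had 2 rises, of Etv4 (0.75) and Ier3 (0.68), 6 adjusted over the list alone, and a median of 0.18 (adjusted p = 0.00516, and adjusted p = 0.224 with an estimated correlation). Pluripotency genes (30) had a median of -0.23 (adjusted p = 0.0367, and adjusted p = 0.637 with an estimated correlation). Among them Utf1, a chromatin factor of stem cells, rose by 0.59 and Dppa3 fell by 1.13, and 1 rose and 2 fell adjusted over the list alone. The 22 Oct3/4-Sox2 targets were at -0.19 (adjusted p = 0.0367, and adjusted p = 0.572 with an estimated correlation), with the rise of Utf1 and a fall of the Nodal antagonist Lefty2 (-0.58), and 1 rise and 3 falls adjusted over the list alone. The other 17 lists did not differ as sets. They held rises of Nes (1.05) and Ccnd1 (0.92) and falls of Col4a2 (-1.48), Cxcl10 (at least 2.71-fold) and Zfy1 (-0.71), among others. Epithelial markers, 1 of these lists, had a median of 0.04, with 4 rises and 3 falls adjusted over the list alone.

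**Figure D4:**
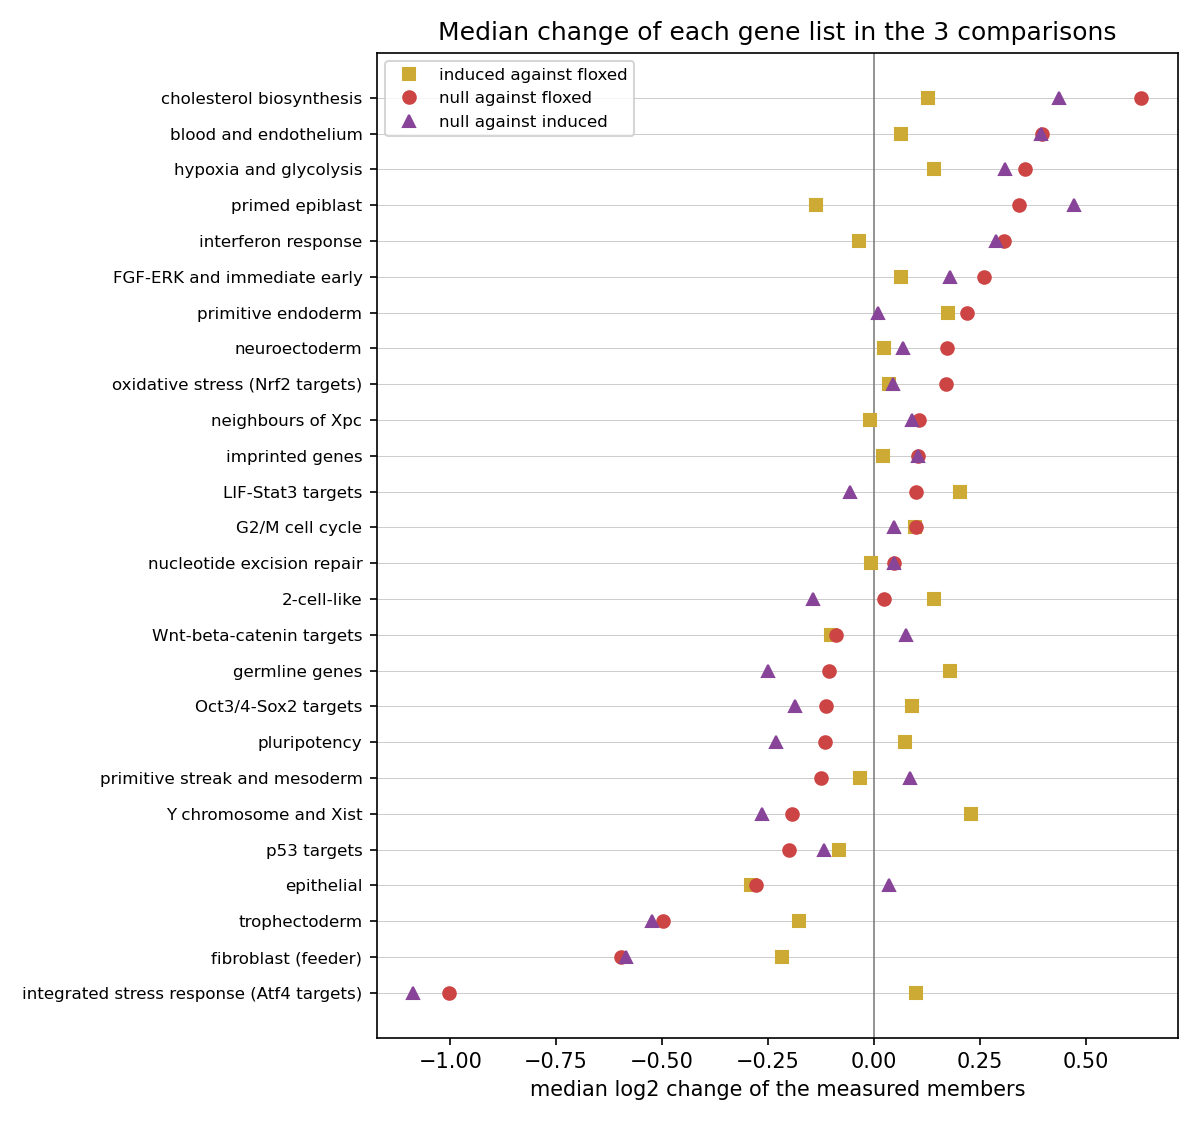
Median log2 change of the measured genes of each of the 26 lists in the 3 comparisons, with log2 change and list as the axes and 1 point per list and comparison. Atf4 targets lie at -1.0 and -1.09 in the comparisons with null cells and at 0.10 between induced and floxed cells, where the median was -0.23 without floxed array 3.

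With limma 4749 of the 19914 genes had an unadjusted p under 0.05 between null and induced cells, and 32 of the rises and 146 of the falls were at least 2-fold. The groups' arrays did not overlap in any of the 438 genes, again selected on the same arrays, against 10% by chance in unselected genes. With median centring 117 rose and 372 fell. Without floxed array 3 the count was 3610, with all 438 among them. No floxed array enters this difference, so floxed array 3 changed the count only through the spread shared by the 3 groups. With only the 6 arrays compared the count was 2780. Without induced array 1, 2 or 3 it was 82, 61 or 69, and without null array 1, 2 or 3 it was 92, 86 or 143. Within slide 3, where 3 induced and 2 null arrays were compared, a setting chosen after seeing the data, 2465 genes passed (1049 rose and 1416 fell), 430 of the 438 among them. There Acta2 stood at -2.90, Krt18 at -1.45 and Pou3f1 at 1.69, and the medians at -1.09 for Atf4 targets, -0.65 for fibroblast and -0.56 for trophectoderm markers, the last at a camera adjusted p of 0.0537 (0.000104 to 0.224 over the alternatives). The medians within that slide were 0.49 for primed epiblast, 0.46 for cholesterol biosynthesis, 0.34 for hypoxia and glycolysis, 0.20 for FGF-ERK genes, -0.18 for pluripotency and -0.17 for Oct3/4-Sox2 targets. Oct3/4-Sox2 targets and trophectoderm markers did not pass camera within that slide or with slide as a block, while interferon genes, at 0.30 in both settings, did. The calls of pluripotency and Oct3/4-Sox2 targets were also lost without induced array 1 (-0.21 and -0.16) or null array 3 (-0.18 and -0.17), and the latter without null array 2 (-0.18). Without floxed array 3 interferon genes passed (0.29), without induced array 3 germline genes (-0.27), and without induced array 1 or null array 1 Y chromosome and Xist (-0.37 each).

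The last question was how far the changes against floxed cells were shared. Tmem95 was the 1 gene that passed in both comparisons, but it lay below background on every null and every floxed array, so no size is given for null cells (limma adjusted p = 0.0448). That call was lost in 18 of its 22 alternatives, among them leaving out any array other than floxed array 3. Across genes the correlation of both sets of changes was r = 0.247 (Spearman 0.239), and both share the 3 floxed arrays. In 100 simulations with no true change, the shared arrays alone gave a mean r of 0.499, with 66.6% of genes of the same sign against 58.7% in the data, and 0 genes in both against 1. The simulations left out slides, although arrays of a slide correlated at 0.512 in the fit with slide as a random block. The covariance of 0.0216 was near the simulated 0.0222, but the simulations gave all groups the same spread. The shared floxed arrays had the largest median SD over genes, 0.177 against 0.116 in induced and 0.145 in null arrays. Simulated r and covariance may thus be too low, so they do not tell how far changes were shared. Of the genes that passed between null and floxed cells, 78.5% had the same sign in induced cells, a share the common arrays also raise. Lists of these sizes drawn independently would share 0.00738 rising genes. The 3 floxed arrays were too few to split between both comparisons. Without floxed array 3 the genes in both numbered 125, and with slide as a block 13.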

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

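The settings with slide as a random block and within slide 3 were chosen only after the results were seen. Main counts of genes that passed were 1 for induced against floxed, 368 for null against floxed and 438 for null against induced cells, 1 gene passed in both comparisons with floxed cells, and 11, 9 and 9 lists passed. Unless the construction shows it, the cause of a move was not tested. No named gene that had passed changed sign in any setting, while genes that had not passed, such as Klf4 and Esrrb, changed sign in some. The 101 named calls were kept in 1663 and lost in 674 of their settings, most often without the filter on dim probes (64) or without null array 2 (58), and never with array weights or without floxed array 3. The 24 named results that had not passed, each a gene in 1 comparison, did so 23 times over all their settings. Calls of lists (29) were kept in 610 settings and lost in 118. Xpc kept its calls against floxed cells in every setting run. Replicate numbers showed no pairing of samples, though 3 arrays per group cannot exclude it. Deviations of arrays with equal numbers correlated between -0.106 and 0.0871, and the equal number was the best match in 3 of 9 cases. Signal over background limits the low side of falls such as those of Csf1 and Cdx2, where the null arrays bound the change from 1 side alone.

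Without the filter on dim probes, where 35017 genes were tested, 0, 76 and 63 genes passed in the 3 comparisons and 0 in both. The induced count was 0 with quantile normalization, normexp, the series matrix, the filter over all 9 arrays, and trend with robust, and 3 with median centring. Genes in both numbered 0 in all of these, with every probe on its own, and with only the 6 arrays compared. Normexp gave 570 genes for null against floxed. With only the 6 arrays compared 82 genes passed for null against floxed, 2780 for null against induced, and 7 lists for induced cells. Trend with robust gave 910 and 868 in the comparisons with null cells. Array weights gave 1121, 6008 and 4135 genes and 696 in both, with floxed array 3 down to a weight of 0.158. The replicate block gave 166 and 188 in the comparisons with null cells. Slide as a block gave 174, 50 and 3249 genes and 13 in both, slide as a random block 0, 103 and 1812 and 0 in both, and the fit within slide 3 gave 2465. Camera with an estimated correlation called 0, 0 and 0 lists, and fry 0, 10 and 6.

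Some list results reversed, by the direction of camera. For induced against floxed cells, slide as a block gave -0.0021 for G2/M, -0.35 for cholesterol biosynthesis, -0.27 for hypoxia and glycolysis, -0.44 for interferon (where the median was below 0 before) and -0.34 for 2-cell-like genes, slide as a random block gave -0.028 for cholesterol biosynthesis, and array weights -0.24 for Atf4 targets. With each array left out, the induced median ran from -0.23 to 0.23 for Atf4 targets and from -0.044 to 0.32 for LIF-Stat3 targets, each lowest without floxed array 3. The 2-cell-like median for null against floxed cells ran from -0.19 to 0.36, highest without floxed array 3, where the direction of camera turned upward. Primed epiblast genes gave -0.071 for null against floxed cells with slide as a block.

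With each array left out in turn, counts ran from 0 to 145 (induced against floxed), 79 to 4944 (null against floxed), 61 to 3610 (null against induced) and 0 to 125 (both), the highest in each case without floxed array 3. Lists ran from 6 to 13, 9 to 11 and 7 to 10. Xpc changes ran from -1.51 to -1.30, -1.88 to -1.54 and -0.50 to -0.17, the last past the test without null array 1.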

Other observations

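The tests of an exchange of arrays, of the loss of Xpc, of the share of fibroblasts and of YAP-TEAD and SRF-MRTF targets were chosen only after the results were seen. Targets of YAP-TEAD and of SRF-MRTF, transcription factors that respond to cell shape and actin, were gathered as a list after the falls of Acta2, Tagln and Ankrd1 had been seen, leaving out genes already named. Of 35 such targets, 24 lay lower in null than in floxed cells, 8 fell (Anxa1, Axl, Cald1, Ccn1, Cnn2, F3, Tgfb1i1 and Tpm1) and 1 rose. Camera gave p = 1.04e-05 for null against floxed cells, and p = 0.0593 with an estimated correlation. By kind, camera gave p = 0.018 for 14 YAP-TEAD targets (median -0.29) and p = 3.52e-05 for 21 SRF-MRTF targets (median -0.26), and with an estimated correlation p = 0.106 and p = 0.0787. For induced against floxed cells 26 of the 35 lay lower (camera p = 0.000307, and p = 0.106 with an estimated correlation), with p = 0.148 for YAP-TEAD targets, and p = 0.00016 for SRF-MRTF targets (0.102 with an estimated correlation). For null against induced cells 21 lay lower, 6 fell and 1 rose (camera p = 0.00727, and p = 0.207 with an estimated correlation). There the YAP-TEAD median was -0.11, with 8 of 14 lower (camera p = 0.133), and the SRF-MRTF median -0.02, with 13 of 21 lower (camera p = 0.0136, and p = 0.253 with an estimated correlation).

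The splits of the 6 arrays of each comparison are 10, too few for a share under 0.05. The real split gave 1 gene for induced against floxed cells and the highest of the others 0, 368 against 1 for null against floxed cells, and 438 against 0 for null against induced cells. In each comparison 1 split, the real one, gave as many genes.

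Floxed array 3 lay nearer the null arrays than floxed arrays 1 and 2 did. An exchange with a null array is argued against, since its Xpc signal lay 1.02 on the log2 scale above the highest null array and no null array lay at the floxed level, though it was also 0.387 below the lowest other floxed array. A difference between slides as the whole cause is argued against too: across genes, its distance from floxed arrays 1 and 2 correlated at r = 0.572 with the difference of null and induced arrays within slide 3, which holds no slide difference. A slide part may remain, since the second principal component sets both arrays of slide 2 apart. A difference in the state of these cells that needs no deletion stays open and was not tested.

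Targets of Atf4 were lower in null cells. A difference between slides as the whole cause is argued against by the median of -1.09 within slide 3. Loss of Xpc may account for part of it, but the list lay at -0.76 in floxed array 3 against floxed arrays 1 and 2, and the null arrays lay at -0.30 from floxed array 3. The Xpc signal of floxed array 3 lay above every null array but below the other floxed arrays, so a partial loss there is not excluded. Induced cells, with the Xpc probe at 38.4% of the floxed level, had a median of 0.10 (-0.23 without floxed array 3 and 0.53 with slide as a block). Null cells still held 31.1% at that probe, and Xpc protein was not measured here. The induced cells therefore cannot tell whether loss of Xpc lowers these targets. Lasting loss of Xpc, subcloning, the time since the deletion and a difference in culture stay open and cannot be told apart.

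Fibroblast and trophectoderm markers were lower in null cells by their medians, though 6 of 17 trophectoderm markers lay higher than in floxed cells. Within slide 3 the higher of both list medians was -0.56, which argues against the slides as the whole cause. That median was of the trophectoderm markers, which did not pass there (camera adjusted p = 0.0537), so the argument is weaker for them. Fewer feeder fibroblasts would not lower keratins, which fibroblasts largely lack, yet the smallest fall among Krt8, Krt18 and Krt19 was -1.56. These keratins were picked after their falls had been seen, so the argument covers them alone and is no independent test. Of 13 epithelial markers 6 lay higher in null than in floxed cells. For the fibroblast markers alone a smaller share of fibroblasts may still hold, as 10 of 13 lay lower, while Thy1 (1.37), Cxcl12 (0.88) and Mmp2 (0.17) lay higher without passing over all genes (Thy1 rose adjusted over the list alone, as did Thy1 and Cxcl12 against induced cells). A further 12 of the 25 listed, the abundant Lum, Dcn and Postn among them, had no probe kept by the filter on signal over background. Their absence may mean a dim signal in every group and does not speak for this explanation. Lower YAP-TEAD and SRF-MRTF activity is another candidate explanation, left open by a held-out median of -0.26 against floxed and -0.04 against induced cells, and subcloning stays open as untested.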
